A study of Mus musculus with 18 samples.

How the data were processed

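The data were RNA sequencing values of epididymal adipose tissue and liver from mice on a normal diet, high-fat diet-prone mice and high-fat diet-resistant mice, with 3 libraries in each of 6 groups. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made from mRNA with a TruSeq kit. The authors deposited 1 table of FPKM values, which scale fragments by transcript length and by the fragments mapped in a library, with 18 library columns. Per the submitters' processing notes, CASAVA 1.8.2, STAR 2.4.0 and Cufflinks 2.1.1 were used. Their roles and settings, the genome build, the annotation and the strand setting are not given in the sources used here, so no coordinates are printed and antisense or overlapping genes cannot be told apart. The table held 23474 gene identifiers, of which 22671 were named, with a transcript length and GC content, from the GENCODE M21 annotation of the reference. The other 803 kept their identifier.

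Groups and replicate numbers were taken from the titles of the samples. The labels do not state that each library came from a separate mouse, so p-values measure the spread between these samples, which may be technical in part. FPKM carries no total count and no counting interval could be given. Low FPKM values step by the worth of a fragment, and these steps gave the depth relative to another library of the tissue: 0.88 to 1.10 in liver, and in eWAT 0.94 to 1.21 for the 5 libraries with a clear peak, against HR 3. No clear peak was found for eWAT ND 1, ND 2 and HP 1. An FPKM value depends on all other transcripts of its library, so RNA of another tissue lowers every value of the main tissue.

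Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a trend of the variance over expression. Fold changes on this scale understate the change of low genes. Genes with at least 1 FPKM in at least 3 of the 9 libraries of a tissue were kept, the 3 groups of a tissue shared 1 fit, tests were two-sided, and Benjamini-Hochberg adjustment was made over the genes tested, at a threshold of 0.05. The difference between tissues was tested as the difference of their contrasts over all 18 libraries. Both tissues shared 1 estimate of the spread per gene there. It can understate the spread in eWAT, whose libraries resembled each other less than those of liver. A set of 37 gene lists was written from general knowledge and tested with camera at a preset correlation of 0.01 and with an estimated correlation, for lists of at least 3 tested genes. Counts "adjusted over the list alone" correct for the members of the list and no other gene. The tests, lists, alternatives and naming rule were fixed before the data were examined.

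Named genes followed a rule. Up to 8 higher and 8 lower genes with the largest log2 change were taken in each comparison, among genes past the threshold with a mean of at least 5 FPKM in the higher group, groups that did not overlap, and no predicted or clone name. Chance gives groups that do not overlap in 10% of genes at 3 against 3. Fixed genes of each tissue and up to 4 members of each list described were added, and where fewer than 6 genes met the rule, the 4 higher and 4 lower genes with the smallest p. For the tissue difference up to 5 genes of each sign were taken. In eWAT the rule was also applied to the fit over 7 libraries, which was added after spermatid transcripts had been seen. That fit has 2 ND and 2 HR libraries, so chance gives groups that do not overlap in more than 10% of its genes. Lcn8, Gpx5 and Crisp1 were named after their values were seen.

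Alternatives fixed at the same time were a pseudocount of 0.1, no filter on low values, quantile normalization, rescaling to the same sum, a fit of the compared groups alone, no variance trend, the replicate number as a block, and leaving out each library. Added after seeing the data were the fits without eWAT ND 1 and HR 2 or without the 4 libraries over 1000 FPKM of spermatid transcripts, and a correction of each library for smooth trends in transcript length and GC content. The pipeline was tested on simulated data with 200 changed genes. In liver it called 82% of genes changed by 1 on the log2 scale and 98% of those changed by 2, with 11 unchanged genes called among 10633. In eWAT it called 45% and 79% over 7 libraries (8 unchanged genes called among 13054), and 0% of either over 9 libraries. Figures were drawn with matplotlib 3.10.9. A few genes that the naming rules picked out are not reported here.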

Results

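Messenger RNA was sequenced from epididymal adipose tissue (eWAT, the fat pad attached to the epididymis) and from liver of male C57BL/6J mice. Per the labels, the mice were 17 weeks old and had been on their diets for 12 weeks from 5 weeks of age. Each tissue had 3 groups of 3 libraries, 18 in all: mice on a normal diet (ND), and mice on a high-fat diet that were prone (HP) or resistant (HR) to it. The labels describe a random division into the groups and do not say how prone and resistant animals were told apart, nor whether libraries with the same number in the 2 tissues came from the same mouse. The stated aim of the study was to measure expression linked to lipid and glucose metabolism in mice that respond differently to a high-fat diet. The values were FPKM, so the absolute depth of each library is unknown. From the smallest steps of low values, the liver libraries had relative depths of 0.88 to 1.10 against liver ND 2.

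Liver libraries resembled each other closely, with correlations across genes of 0.97 to 0.994. Among the eWAT libraries, ND 1 and HR 2 stood apart, with median correlations to the other eWAT libraries of 0.607 and 0.713. These libraries carried transcripts of spermatids, the haploid germ cells of the testis. The summed FPKM of the spermatid genes Prm1, Prm2, Tnp1 and Tnp2 was 92413 in ND 1, 11231 in HR 2, 2282 in ND 3 and 1738 in HP 1, and no more than 128 in the remaining 5 eWAT libraries. The epididymal secretory genes Lcn8 and Gpx5 reached 8812 and 6364 FPKM in ND 1, and Crisp1 reached 1172 FPKM in HP 2. Adipocyte transcripts (Adipoq, Fabp4, Plin1 and Cidec) summed to 3533 FPKM in ND 1 and 4760 in HR 2, against 14984 to 29573 in the other 7 libraries. Each eWAT comparison is therefore given over all 9 libraries and again over the 7 libraries without ND 1 and HR 2, a choice made after these values were seen.

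**Figure D1:**
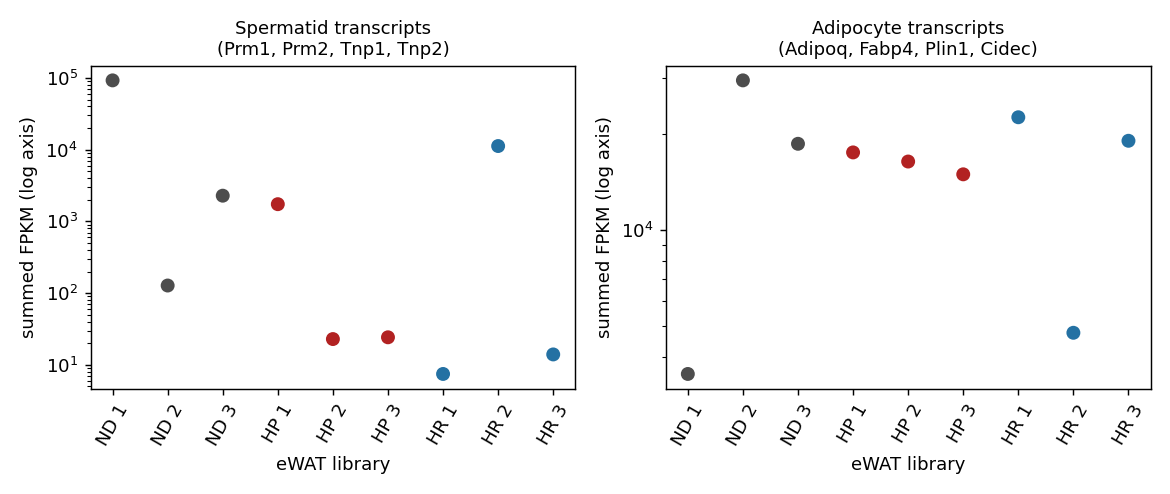
Summed FPKM (log axis) of 4 spermatid genes (left) and of 4 adipocyte genes (right) in each of the 9 eWAT libraries, 1 point per library, coloured by diet group (ND grey, HP red, HR blue). ND 1 and HR 2 had the highest spermatid sums, 92413 and 11231, and the lowest adipocyte sums, 3533 and 4760.

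The first comparison in eWAT set prone mice against mice on normal diet. Among the genes that rose in HP were markers of lipid-laden macrophages. Gpnmb (ENSMUSG00000029816), a glycoprotein of lipid-laden macrophages, averaged 844 ± 132 FPKM in HP (SD, n = 3) and 4.02 ± 1.86 in ND (SD, n = 3), a log2 difference of 7.45 (SE 0.74, limma adjusted p = 0.0196). Mmp12, a macrophage elastase, rose by 7.90 on the log2 scale, and Trem2, a lipid receptor of macrophages, by 6.04 (adjusted p = 0.0214). Atp6v0d2, Adam8, Il1rn, Ubd and Rgs1 rose by 5.45 to 6.13. Among the genes that fell, Cfd (ENSMUSG00000061780), which encodes the adipokine adipsin, had 3580 ± 514 FPKM in ND and 313 ± 53.5 in HP (log2 difference -3.52, SE 0.69, adjusted p = 0.0475). Agt, the precursor of angiotensin, fell by 3.04, from 109 ± 10.4 to 12.8 ± 3.92 FPKM. Dpm1, Spaca6 and Immp2l also fell, with log2 differences of -2.0, -1.95 and -1.33. Crygn was listed at 0 in all 3 HP libraries and at 14.5, 6.89 and 5.52 FPKM in ND 1, ND 2 and ND 3.

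By gene list, 11 of 19 tested genes of lipid-associated macrophages rose and none fell (16 adjusted over the list alone). Of 23 general macrophage genes 8 rose (16 adjusted over the list alone), among them Itgax (5.33), Ctss (5.27), Adgre1 (4.87) and Cd68 (4.84). The camera test placed both lists above other genes, with adjusted p = 1.45e-17 and 1.43e-11, and with an estimated correlation both had adjusted p = 0.362. With quantile normalization 2 lipid-associated and 0 general macrophage genes passed, at medians of 4.41 and 2.50 against 4.57 and 2.55, and so did 0 lysosomal genes and 1 cytokine or chemokine gene. Of 28 lysosomal genes 4 rose (21 adjusted over the list alone), including Ctsk (5.05), with a median log2 difference of 1.88 and adjusted p = 0.383 with an estimated correlation. Il1rn, Ccl2, Ccl3 and Tnf rose among 22 cytokine and chemokine genes (adjusted p = 0.362 for the list with an estimated correlation). Leptin (Lep) had 1090 ± 169 FPKM in HP and 216 ± 180 in ND (log2 difference 3.48, SE 1.40, adjusted p = 0.387), and Adipoq, Pparg, Slc2a4, Fasn and Mest did not pass either, with adjusted p from 0.587 to 0.99. Ucp1 stayed at or below 5.05 FPKM in the ND and HP libraries (adjusted p = 0.947) and had 32.5 FPKM in HR 1.

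In all, 298 genes were higher and 6 lower in HP among 14430 tested at an adjusted p of 0.05 (limma, log2 of FPKM + 1). Leaving out any of ND 2, ND 3, the 3 HP libraries or HR 1 left 0 calls (925 to 2324 at an unadjusted p under 0.05, limma), without HR 3 there were 134, and without HR 2 there were 593. Quantile normalization left 16 and a pseudocount of 0.1 FPKM 162. With libraries rescaled to the same sum the median change of all genes was 0.404 for HP against ND and 0.443 for HR against ND.

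Over the 7 libraries, 2047 genes were higher and 966 lower in HP than ND among 13054 tested, and 303 of the 304 genes called with 9 libraries were called in the same direction. Of 28 lysosomal genes 27 rose and none fell, as did 17 of 19 lipid-associated macrophage genes (adjusted p = 0.235 for both lists with an estimated correlation). Of 23 general macrophage genes 17 rose and 1 fell, and of 27 matrix and fibroblast genes 18 rose, such as Timp1 (3.86) and Col1a1 (2.13) (adjusted p = 0.239 for both lists with an estimated correlation). Cell cycle genes rose for 14 of 21, such as Ube2c (2.18) and Mki67 (1.88) (adjusted p = 0.328 with an estimated correlation). Of 24 adipocyte identity genes 15 fell and 3 rose, with Adrb3, the lipolytic adrenoceptor, at -2.33 and Retn, resistin, at -1.91 (adjusted p = 0.269 with an estimated correlation). Adipoq fell by 1.19 (SE 0.21, adjusted p = 0.00941), while Lep rose by 1.76 (SE 0.22, adjusted p = 0.00211). Of 21 genes of branched-chain amino acid catabolism 12 fell and none rose, led by Aldh6a1 (-1.56) and Ivd (-1.41) (adjusted p = 0.239 with an estimated correlation). Of 20 glucose and insulin genes 12 fell and 1 rose (adjusted p = 0.167 with an estimated correlation). Among the former were Pck1, which makes phosphoenolpyruvate for glyceroneogenesis (-3.05), and Slc2a4, the insulin-responsive glucose transporter (-0.93, adjusted p = 0.0481, against 0.33 over 9 libraries, adjusted p = 0.879). Over 9 libraries 1 adipocyte gene was lower, and no branched-chain or glucose and insulin gene, at list medians of 0.01, -0.01 and -0.25 against -0.9, -0.86 and -1.02 over 7. Of the cell cycle and matrix genes 3 each rose over 9 libraries. Cyp2e1 had the largest fall that met the naming rule (-4.07), from 1612 and 1492 FPKM in the ND libraries to 94.0 ± 25.0 in HP (SD, n = 3).

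Cholesterol genes also rose over the 7 libraries, 13 of 23 against 1 that fell (2 and 0 over 9 libraries), led by Dhcr7 (2.16) and Msmo1 (1.61) (adjusted p = 0.239 with an estimated correlation). Among markers of other cell types, 6 of 8 neutrophil and mast cell genes rose and 4 of 9 mesothelial genes fell (adjusted p = 0.239 and 0.395 with an estimated correlation). No gene of 14 endothelial or 8 T and natural killer cell genes passed, at medians of -0.07 and -0.09. The 6 epididymis and testis genes tested had a median of -2.29 and none passed. ND 3 and HP 1, which carried spermatid transcripts, were among the 7 libraries. So was HP 2, where 7 epididymal genes, Crisp1 among them, summed to 1287 FPKM. Adjusted over the list alone, 17 lipid-associated macrophage, 18 macrophage, 28 lysosomal, 15 cell cycle, 21 matrix and 16 cholesterol genes were higher, and 16 adipocyte, 17 branched-chain amino acid and 12 glucose and insulin genes were lower. With an estimated correlation no list passed. The count of genes was 1508 without HP 3.

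**Figure D2:**
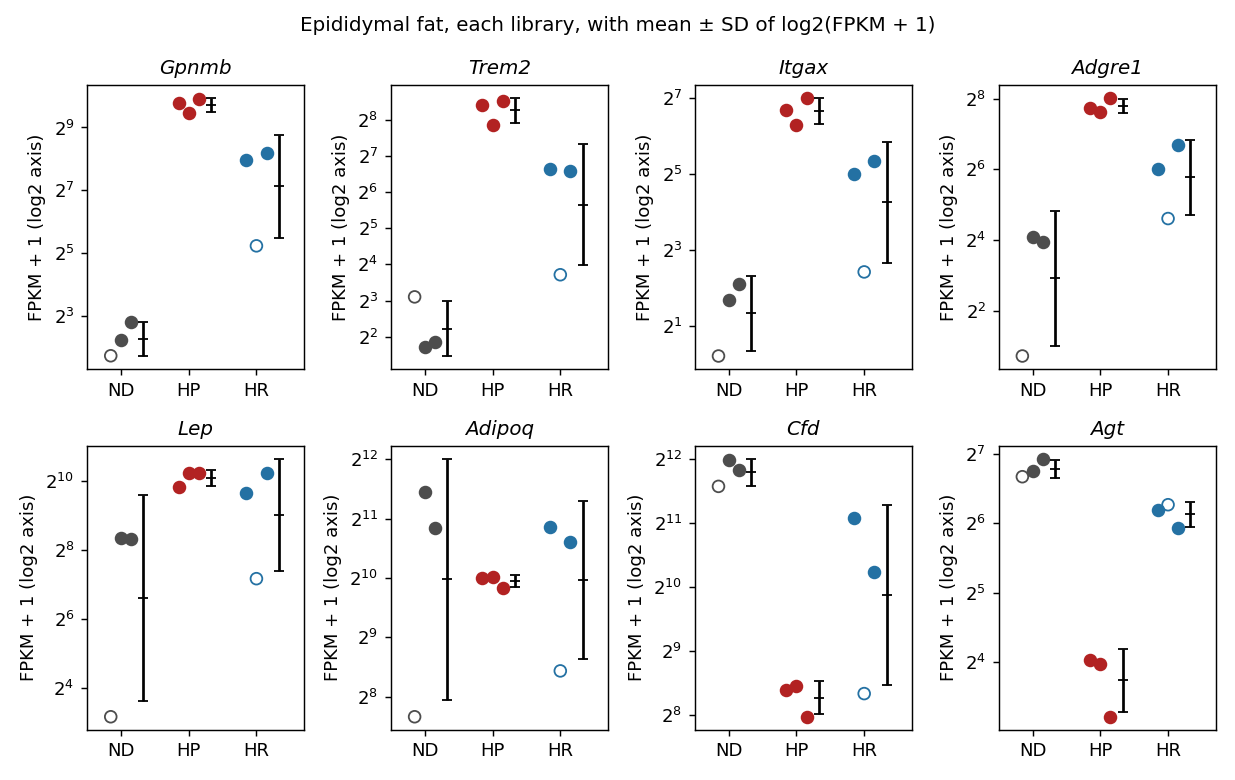
FPKM + 1 (log2 axis) of 8 genes in the 9 eWAT libraries by diet group, 1 circle per library, with open circles for ND 1 and HR 2 and black bars for the mean ± SD of log2(FPKM + 1) over all 3 libraries of a group. For Gpnmb the HP mean was 844 FPKM and the ND mean 4.02, with the HR libraries between them, while Cfd and Agt were lowest in HP.

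Resistant mice were next compared with mice on normal diet. Over 9 libraries no gene passed in eWAT with limma (392 had an unadjusted p under 0.05). The genes with the smallest p were Gpnmb, with 192 ± 137 FPKM in HR (SD, n = 3) and a log2 difference of 4.86 (SE 0.74, adjusted p = 0.777), Saa3 (3.55), F7 (3.41) and Il1rn (3.14) on the higher side. On the lower side were Crygn, listed at 0 in all 3 HR libraries, Nat8f1 (-1.64), Med18 (-1.41) and Slpi (-1.64), with adjusted p from 0.24 to 0.99.

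Over the 7 libraries 502 genes were higher and 38 lower in HR, against 341 in all with no filter on low values. Gpnmb rose by 5.55 (SE 0.23, adjusted p = 0.000665), Mmp12 by 4.84, Trem2 by 4.83 and Atp6v0d2 by 4.56. The acute-phase gene Saa3 rose by 4.13 and the coagulation factor F7 by 4.12. Of 19 lipid-associated macrophage genes 14 rose, as did 11 of 23 macrophage genes, 16 of 28 lysosomal genes and 11 of 27 matrix and fibroblast genes, and none of these lists had a member that fell. The adjusted p with an estimated correlation was 0.309 for the lipid-associated macrophage, lysosomal and matrix lists and 0.342 for macrophage genes. Adjusted over the list alone, 16 lipid-associated macrophage, 13 macrophage, 21 lysosomal and 18 matrix genes were higher. Lep rose by 1.61 (adjusted p = 0.0164), and it was the gene of 24 in the adipocyte list to pass. Adipoq had a log2 difference of -0.41 (SE 0.23, adjusted p = 0.411). Falling genes included Nrg4, an adipokine (-1.31), Mogat1, which makes diacylglycerol (-1.47), and Irf4 (-1.49). The count was 274 without HP 3 and 305 without HP 2. It was 1307 without ND 3, 86 without HR 3 and 232 without HR 1, where 1 library stood for the group and the spread came from the other groups, and the full 7-library fits hold 2 libraries each of ND and HR.

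HP and HR were then set against each other, which asks how prone and resistant mice on the high-fat diet differ. Over 9 libraries no gene passed in eWAT with limma (679 had an unadjusted p under 0.05). Among those with the smallest p were Htr2b (2.39), Oit3 (1.71), Zranb3 (2.59) and Prkcb (1.79) on the higher side and Agt (-2.38), Spaca6 (-1.17) and Pdk2 (-1.37) on the lower, with adjusted p from 0.649 to 0.792. Over the 7 libraries 549 genes were higher and 294 lower in HP, against 337 and 400 with quantile normalization and 203 and 90 with no filter on low values. Macrophage genes were higher in HP for 15 of 23 members, such as Cd68 (1.69) and Itgax (1.49), and for 13 of 19 lipid-associated members, such as Mmp12 (2.07) (adjusted p = 0.22 and 0.215 with an estimated correlation). Lysosomal genes were higher for 15 of 28 (adjusted p = 0.215 with an estimated correlation), and 2 of 14 endothelial genes were lower, at a list median of -0.67 (adjusted p = 0.22 with an estimated correlation). Cell cycle genes were higher for 9 of 21, including Top2a (1.5) (adjusted p = 0.238 with an estimated correlation). Adipocyte identity genes were lower for 10 of 24, with Cfd at -2.38 and Adrb3 at -1.97, and glucose and insulin genes for 7 of 20, with Pck1 at -1.95 and Slc2a4 at -1.21 (adjusted p = 0.22 and 0.144 with an estimated correlation). Lep did not differ past the threshold (0.15, SE 0.22, adjusted p = 0.733). Zranb3 (2.58), Timp1 (2.11), Htr2b (2.1) and Tph2, a serotonin-synthesizing enzyme (2.08), were among the genes higher in HP, as were the near-identical Rnaset2a and Rnaset2b, which reads may not tell apart. Cyp2e1 (-2.76), Agt (-2.31), Eif4ebp3 (-2.22) and Mycl (-1.90) were lower. Adjusted over the list alone, 17 macrophage, 16 lipid-associated macrophage and 15 cell cycle genes were higher, and 16 adipocyte and 11 glucose and insulin genes were lower. The count was 0 without any of HP 1, HP 3, HR 1 or HR 3 (1828 to 2433 at an unadjusted p under 0.05, limma), the last 2 with 1 HR library left, 179 without HP 2, 1829 without ND 2 and 1922 without ND 3.

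In liver the comparison of HP with ND gave the most calls. Cfd, which fell in eWAT, rose in liver from 1.87 ± 1.20 to 136 ± 72.3 FPKM (SD, n = 3 each; log2 difference 5.48, SE 0.42, limma adjusted p = 5.96e-05). Gdf15, a stress-induced hormone, rose by 3.71, from 1.36 ± 0.49 to 29.9 ± 6.95 FPKM. The female-biased cytochrome P450 gene Cyp2b9 rose by 5.01, and Gsta1, Scand1, Lgals1 and Cyp2a4 by 3.40 to 4.55. Of 7 female-biased genes in the list 3 rose and none fell, at a median of 0.18 (-0.03 after rescaling to the same sum). Hsd3b5, a male-specific steroid dehydrogenase of liver, fell from 61.2 ± 16.5 to 0.964 ± 1.40 FPKM (log2 difference -5.17, SE 0.38, adjusted p = 5.66e-05). Serpina1e, Slco1a1, Mup7, Cyp4a12b, Lepr, Mup1 and C8b fell, with log2 differences of -3.79 to -2.39. Mup, Cyp2a, Cyp4a, Gsta and Serpina1 genes have near-identical copies whose reads FPKM estimation can split among them, so their values are uncertain.

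Cholesterol synthesis and uptake genes rose in liver for 18 of 24 members (18 adjusted over the list alone), led by Fdps (2.20), Msmo1 (2.04), Nsdhl (1.83) and Hmgcs1 (1.64), and 1 fell. The list had adjusted p = 3.46e-08, and adjusted p = 0.299 with an estimated correlation. Of 33 oxidation and PPAR alpha target genes 16 fell and 4 rose, with Cyp4a31 (-2.28), Ehhadh (-2.06) and Cyp4a14 (-1.95) lowest (16 lower adjusted over the list alone, adjusted p = 0.469 with an estimated correlation). Cpt1a, which admits fatty acids to mitochondria, fell by 0.96. Lipid droplet genes rose for 11 of 24 and fell for 2, with Cidea at 3.17, Plin4 at 2.86, Cidec at 1.22 and Cd36 at 1.04 (12 higher adjusted over the list alone, adjusted p = 0.19 with an estimated correlation). Adipocyte identity genes rose for 8 of 14 and fell for 1, or 4 and 2 after rescaling (adjusted p = 0.349 with an estimated correlation), and the 4 adipocyte transcripts summed to 107 to 152 FPKM in the HP livers and 36.7 to 64.8 in ND. Fasn rose by 1.85 and Srebf1 by 0.88, while Scd1 did not pass (0.22, adjusted p = 0.624). The lipogenesis list had 8 higher and 4 lower of 19 (camera adjusted p = 0.279), and its median of 0.22 was 0 after rescaling. Among 23 glucose and insulin genes 11 fell and 1 rose. The gluconeogenic genes Pck1 and G6pc fell by 1.34 and 1.18 (adjusted p = 0.0552 for the list, and 0.631 with an estimated correlation).

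Of 21 male-biased genes 14 fell and none rose (16 adjusted over the list alone), a list with adjusted p = 2e-07, and adjusted p = 0.469 with an estimated correlation. Of 30 xenobiotic genes 14 rose and 4 fell, including Gstm3 (3.05) and Cyp2a5 (2.64) (adjusted p = 0.469 with an estimated correlation). Acute-phase and complement genes rose for 11 of 24 and fell for 4, with Lcn2 at 3.33 and Saa2 at 2.89 (adjusted p = 0.349 with an estimated correlation). Respiratory chain genes coded in the nucleus rose for 50 of 67 members (60 adjusted over the list alone) and fell for 2, by a median of 0.73, with Uqcrq at 1.52 and Ndufb4 at 1.35 (adjusted p = 1.08e-14, and adjusted p = 0.469 with an estimated correlation). Across all genes the fold changes correlated with transcript length at -0.28 and with GC content at 0.258 (Spearman), and 44 members were higher and 2 lower after the correction for both. Ribosomal protein genes, examined after the fact, rose for 29 of 79 and fell for 3. Their median was 0.47, against 0.28 after the length and GC correction and 0.26 after rescaling. Skeletal muscle transcripts (Ckm, Myh4, Tnnt3, Atp2a1 and Tnnc2) summed to 98.9 FPKM in HP 2 and 19.9 in HP 3, and stayed below 1 in the other 7 liver libraries. Immediate early genes rose for 9 of 13, including Jun (1.72) and Egr1 (1.39), and for 5 after rescaling (adjusted p = 0.349 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a log2 difference of -0.48 (adjusted p = 0.222), and Fgf21 rose by 0.83 (adjusted p = 0.0451).

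In liver 1870 genes were higher and 1502 lower in HP than ND among 10633 tested. With each library rescaled to the same sum the split was 1108 higher and 2438 lower, and the median of all genes moved to -0.205, because the HP libraries had higher FPKM sums. The count was 1716 without HP 2, 1862 without ND 1 and 1935 without ND 3. Liver HP 3 lists Alb and mt-Co1 at 0, where the other liver libraries hold at least 21466 and 29610 FPKM, so a 0 in this table can be a failed estimate.

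**Figure D3:**
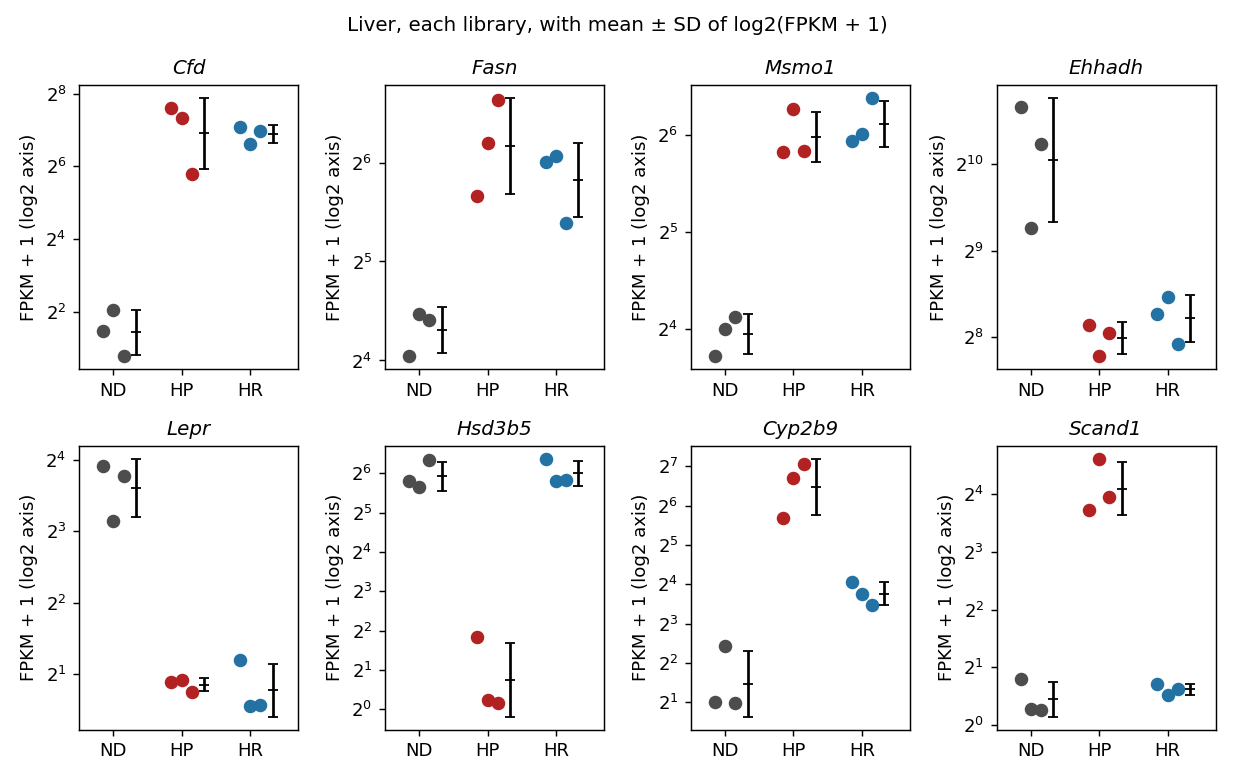
FPKM + 1 (log2 axis) of 8 genes in the 9 liver libraries by diet group, 1 circle per library, with black bars for the mean ± SD of log2(FPKM + 1). Cfd, Fasn, Msmo1 and Cyp2b9 were higher and Ehhadh and Lepr lower in both HP and HR than in ND, while Hsd3b5 and Scand1 differed from ND in HP and did not pass in HR, with Hsd3b5 means of 0.964 FPKM in HP and 64.2 in HR.

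Resistant livers shared part of this profile. Cfd rose by 5.46 (SE 0.42, adjusted p = 0.000151), to 119 ± 19.7 FPKM (SD, n = 3). Cyp2a5 rose by 3.01, Cyp2b9 by 2.29, Tsku by 2.28, Msmo1 by 2.17, and the clock-linked genes Ciart and Rgs16 by 2.44 and 2.38. The leptin receptor Lepr fell by 2.83, Hhex by 1.89, Hspa1b by 1.85, Igfbp1 by 1.79, Cyp4a31 by 1.61 and Apoa4 by 1.60. Lamb3 fell from 17.9 ± 0.623 to 4.87 ± 0.256 FPKM (log2 difference -1.69, SE 0.10, adjusted p = 5.45e-05). Cholesterol genes rose for 15 of 24 (21 adjusted over the list alone) and none fell, with Sqle at 1.79 and Insig1 at 1.64. The list had adjusted p = 3.86e-21, and adjusted p = 0.0631 with an estimated correlation. Of 33 oxidation genes 6 fell and 1 rose, with Ehhadh at -1.83 and Acot1 at -1.31 (11 lower adjusted over the list alone, adjusted p = 0.3 with an estimated correlation). Unfolded protein response genes rose for 8 of 21, including the chaperone genes Sdf2l1 (1.5), Manf (1.48) and Calr (0.87) (12 adjusted over the list alone, adjusted p = 0.3 with an estimated correlation). Fasn rose by 1.51, Srebf1 by 1.33 and Cd36 by 0.71, while Cpt1a fell by 0.62 and G6pc by 1.12. No male-biased gene passed among 21, and no respiratory chain gene among 67, at medians of -0.24 and 0.13. Cidec, Fgf21, Pck1, Cyp7a1 and Scd1 did not pass, with adjusted p from 0.138 to 0.611.

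In total 242 genes were higher and 103 lower in HR than ND in liver, against 158 and 63 after rescaling, 184 and 124 with quantile normalization and 200 in all with no filter on low values. The count was 91 without ND 1, 160 without ND 3, and 134, 123 and 137 without HR 1, HR 2 and HR 3. Of the calls, 206 higher and 81 lower genes were also called in HP against ND, where independent lists would share 42.6 and 14.6. Both comparisons use the same ND libraries: the covariance of their fold changes was 0.108, and 0.0209 in simulations of unchanged groups against those libraries. The ND libraries are too few to split, so part of the excess may come from them. The shared total of 287 fell to 76 without ND 1, 125 without ND 3, and 118, 112 and 117 without HR 1, HR 2 and HR 3. In eWAT over 7 libraries 477 higher and 37 lower genes were shared, where independent lists would share 78.7 and 2.81, with a covariance of 0.432 and 0.101 in the simulations. The 514 eWAT genes called in both HP vs ND and HR vs ND without ND 1 and HR 2 became 84 without HR 3, 230 without HR 1, 269 without HP 3, 299 without HP 2, 1147 without ND 3 and 333 with no filter on low values. Without HR 3, HR 1 or ND 3 that group was 1 library.

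Prone and resistant livers were then compared. Hsd3b5 was lower in HP by 5.25 on the log2 scale (SE 0.38, adjusted p = 0.000146), at 0.964 ± 1.40 FPKM against 64.2 ± 15.4 in HR (SD, n = 3 each). Serpina1e, Mup7, Slco1a1, Mup19, Mup13 and Mup1 had log2 differences of -3.59 to -2.58, and Ece1 of -2.43. Of 21 male-biased genes 10 were lower and none higher (15 lower adjusted over the list alone, adjusted p = 9.36e-08, and adjusted p = 0.306 with an estimated correlation), and 2 were called without HP 2, at a median of -0.82 against -0.97. Scand1 was higher in HP by 3.48, Ly6d by 3.04, Gsta1 by 3.04, Wfdc2 by 2.86, Cyp2b9 by 2.73, Lcn2 by 2.56 and the acute-phase gene Orm2 by 2.50. Respiratory chain genes were higher for 35 of 67 and lower for none, with Cox5b at 2.02 and Ndufb2 at 1.53 (45 higher adjusted over the list alone, adjusted p = 1.41e-17, and adjusted p = 0.306 with an estimated correlation), and 11 were called without HP 2, at a median of 0.48 against 0.58. Matrix and fibroblast genes were higher for 10 of 20, led by Col3a1 (2.03) and Col1a2 (1.86), and for 3 of 19 without HP 2, at a median of 0.66 against 0.76 (17 adjusted over the list alone, adjusted p = 0.306 over all libraries with an estimated correlation). Lipid droplet genes were higher for 6 of 24, including Cidea (1.69), Fabp4 (1.51) and Cidec (1.46), and for 2 without HP 2, at a median of 0.41 against 0.39 (11 adjusted over the list alone, adjusted p = 0.161 over all libraries with an estimated correlation). Fgf21 was higher by 1.35 (adjusted p = 0.0175). Cholesterol genes had 3 higher and 2 lower of 24, and Fasn, Srebf1, Scd1, Pck1, G6pc, Cyp7a1, Cd36 and Cpt1a did not pass, with adjusted p from 0.0778 to 0.892.

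In this comparison 766 genes were higher and 419 lower, against 418 and 781 after rescaling, where the median of all genes was -0.194. The count was 229 without HP 2, 243 without HR 2, 456 without HR 3, 468 without HP 3 and 580 with no filter on low values.

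**Figure D4:**
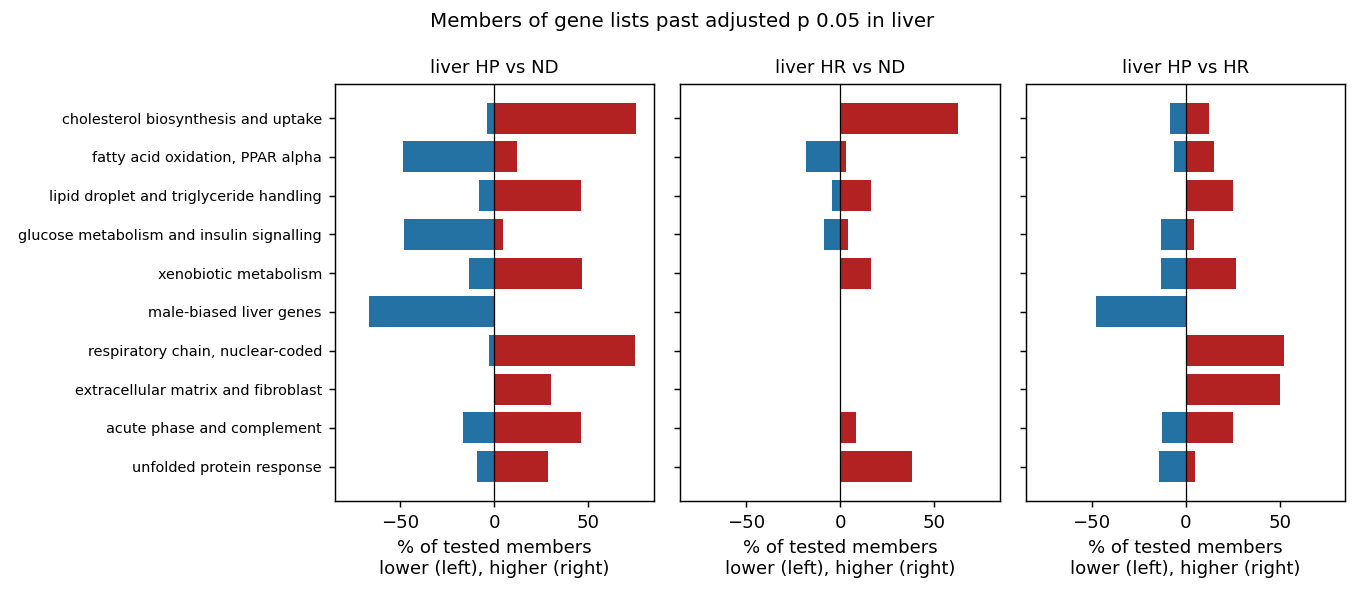
Percent of the tested members of 10 gene lists that were higher (red, right) or lower (blue, left) at an adjusted p of 0.05 in each liver comparison. Cholesterol genes were higher in both high-fat groups against ND (18 and 15 of 24), while male-biased genes were lower in HP against ND (14 of 21) and against HR (10 of 21).

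The difference between the tissues was tested directly for HP against ND over all 18 libraries, with 1 spread per gene shared by both tissues. Cfd differed most, at -9 on the log2 scale for eWAT minus liver (SE 0.82, adjusted p = 0.000127), since it fell in eWAT and rose in liver. Mmp12 (6.67), F7 (5.42), Adgre1 (5.41), Il1rn (5.39) and the lysosomal lipase Lipa (5.34) had the larger change in eWAT. The eWAT change of Lipa by itself did not pass (limma adjusted p = 0.0697). Cidea (-4.20) and Orm3 (-3.99) had the larger change in liver, and Gsta4 (-4.09) had log2 differences of -2.78 in eWAT (adjusted p = 0.0845) and 1.32 in liver. Of 10100 genes tested in both tissues, 301 differed with a positive sign and 78 with a negative sign, against 359 and 29 after rescaling, 1504 and 1132 without eWAT ND 1 and HR 2, and 806 in all with no filter on low values. For HP against HR 5 genes differed: Zranb3, Tk1, Slc25a13 and Dlg3 positively and Agt negatively (-2.48, SE 0.35, adjusted p = 0.0341). There was 1 such gene with a pseudocount of 0.1 FPKM or quantile normalization, 0 after rescaling (465 at an unadjusted p under 0.05, limma), 21 with no filter on low values, and 781 without eWAT ND 1 and HR 2. In eWAT alone, over 9 libraries, none of the 5 genes passed (limma adjusted p = 0.649 to 0.718). In liver alone Zranb3 and Agt did not pass (limma adjusted p = 0.257 and 0.702). Leaving out 1 library moved the count for HP against ND to between 165 (without eWAT HP 3) and 1033 (without eWAT ND 3) and that for HP against HR to between 0 (without any of the 3 HP libraries of either tissue, among others) and 22 (without eWAT ND 1).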

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

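The counts over other splits of the libraries were made after the results had been seen, as was the fit without eWAT ND 1 and HR 2. Between HP and ND, 379 genes changed differently in eWAT and liver by the test of the difference itself, and each gene named here was picked out by that test. Cfd, the gene of adipsin, had a difference of -9 on the log2 scale (eWAT minus liver), with -3.52 in eWAT and 5.48 in liver. Mmp12 (6.67), F7 (5.42), Adgre1 (5.41), Il1rn (5.39) and Lipa (5.34) differed the other way. Their eWAT changes were 7.90, 5.03, 4.87, 5.67 and 4.71 over 9 libraries. Over the 7 libraries they were 6.91, 5.07, 3.78, 5.51 and 3.51. The eWAT change of Lipa did not pass over 9 libraries (limma adjusted p = 0.0697). Cidea had a difference of -4.2, Gsta4 of -4.09 and Orm3 of -3.99. Of 100 splits of the libraries, the real 1 called most genes, a share under 0.05, and the highest of the others called 243. The splits take the libraries as independent, which the labels do not state, so chance was not excluded. The count was 1033 without eWAT ND 3, 900 without eWAT HR 2, 654 without eWAT ND 1 and 598 without eWAT ND 2. It was 165 without eWAT HP 3, 214 without eWAT HP 2, 217 without eWAT HP 1, and 181 to 246 without any of the ND or HP liver libraries.

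Between HP and HR, 5 genes changed differently in the 2 tissues, against 1 with a pseudocount of 0.1 FPKM or quantile normalization, 0 after rescaling (465 at an unadjusted p under 0.05, limma) and 21 with no filter on low values. Zranb3 (2.86), Tk1, thymidine kinase (2.38), Slc25a13 (2.23) and Dlg3 (2.09) had positive differences, and Agt had -2.48. None of these genes passed in eWAT alone (limma adjusted p = 0.649 to 0.718), and Zranb3 and Agt did not pass in liver alone (0.257 and 0.702). Of 100 splits the real 1 called most genes, and the highest of the others called 2. The count was 22 without eWAT ND 1, 11 without eWAT HR 3, 3 without eWAT ND 3 or HR 2, 2 without liver ND 1 and 1 without liver ND 2. It was 0 without any of eWAT HP 1, HP 2, HP 3 and HR 1 or any of liver ND 3, HP 1, HP 2, HP 3, HR 1, HR 2 and HR 3.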

How the results depend on the processing

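The fits without ND 1 and HR 2, without the 4 libraries over 1000 FPKM of spermatid transcripts, and with the length and GC correction were chosen after the data had been seen. Liver HP against ND kept its count within 1.5 times under every setting other than leaving out a library. With a pseudocount of 0.1 FPKM, eWAT HP against ND called 162 genes and the tissue difference in HP against HR 1. Quantile normalization gave 16 and 1 for these. With no filter on low values, liver HR against ND called 200 and HP against HR 580, the 7-library eWAT fits 341 for HR against ND and 293 for HP against HR, the tissue differences 806 and 21, and 165 liver genes, and 333 eWAT genes over the 7 libraries, were called in both HP and HR against ND. Rescaled to the same sum, liver HR against ND called 221, the tissue difference in HP against HR 0, and 180 liver genes were called in both. The length and GC correction gave 1 gene in eWAT HR against ND and 1 called in both eWAT comparisons with ND. The cause of these changes was not tested. Depth limits the low genes, and its absolute value is unknown.

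Without ND 1 and HR 2 the eWAT counts were 3013 (HP against ND), 540 (HR against ND) and 843 (HP against HR), 514 genes were called in both comparisons with ND, the tissue differences called 2636 and 781 genes, and 17 gene lists passed in eWAT HP against HR. Without the 4 libraries ND 2 alone stands for ND and the other groups supply the spread, so differences from ND there rest on 1 library: the counts were 3376, 1479 and 1554, and for eWAT genes called in both HP vs ND and HR vs ND 1232. Slc2a4 in eWAT HP against ND turned from 0.33 to -0.93 without the 2 libraries. Against ND 2 alone it was -1.35, and Pparg was -0.69 where it had been 0.96. Camera with an estimated correlation left 0 gene lists in each of the 6 comparisons.

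With the replicate block, eWAT HP against ND called 0 genes, liver HR against ND 184, the 7-library fits 76 (HR against ND) and 0 (HP against HR), the tissue difference in HP against HR 0, and 156 liver genes, and 76 eWAT genes over the 7 libraries, were called in both. Whether the replicate numbers pair the libraries could not be told. Deviations of same-numbered libraries correlated across genes at -0.843 to 0.625 in eWAT, with 4 of 9 pairs above 0.1. In liver they correlated at -0.348 to 0.428, with 2 of 9 above 0.1. Spermatid-rich samples can set such values in eWAT whatever the number: ND 1 and HR 2 correlated at 0.763.

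Leaving out 1 library gave ranges of 0 (without ND 2, ND 3, HP 1, HP 2, HP 3 or HR 1) to 593 (without HR 2) in eWAT HP against ND, 0 to 27 (without HR 2) in HR against ND and 0 to 0 in HP against HR. In the 7-library fits, where leaving out an ND or HR library leaves 1 in its group, they were 1508 (without HP 3) to 3609, 86 (without HR 3) to 1307 (without ND 3) and 0 (without HP 1, HP 3, HR 1 or HR 3) to 1922 (without ND 3). In liver they were 1716 (without HP 2) to 3543, 91 (without ND 1) to 349 and 229 (without HP 2) to 1424. The tissue differences ranged from 165 to 1033 and from 0 to 22. Genes called in both comparisons with ND ranged from 0 to 27 in eWAT and from 76 to 306 in liver, and eWAT genes called in both HP vs ND and HR vs ND without ND 1 and HR 2 from 84 (without HR 3) to 1147 (without ND 3).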

Other observations

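Tests of other splits, of the mixed tissue, of rescaling and of the macrophage genes were chosen after the results had been seen, while those of transcript length and GC content and of skeletal muscle were set before their result was seen. Over the 7 eWAT libraries, stress and immediate early genes rose in HP against ND for 7 of 17 members and fell for 1, with Atf3, a stress-induced transcription factor, at 4.73, Egr2 at 3.59 and Fos at 3.04 (adjusted p = 0.269 for the list with an estimated correlation). Atf3 also rose in HR against ND (3.06) and was higher in HP than HR (1.67). Clock genes fell for 5 of 18 in HP against ND, including Nr1d1 (-1.1) and Per3 (-0.99), and rose for 1 (adjusted p = 0.0875 for the list, and adjusted p = 0.688 with an estimated correlation). Of 23 lipid droplet genes 9 fell, among them Plin4 (-1.58) and Plin1 (-1.06, against 0.119 over 9 libraries), and 3 rose, among them Plin2 (2.26), with a median of -0.54 (adjusted p = 0.235 with an estimated correlation). Of 8 neutrophil and mast cell genes 4 were higher in HP than HR, including the mast cell genes Mcpt4 (1.79) and Cpa3 (1.76) (adjusted p = 0.215 with an estimated correlation).

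In liver, HP had lower transcripts of Slco1a1 and Cyp7b1, which handle bile acids, than ND (-3.76 and -1.55) and than HR (-3.27 and -1.75), and Nr0b2, a bile acid-responsive repressor, rose against ND (1.63). The bile acid list went both ways, with 4 of 20 higher and 3 lower in HP against ND (adjusted p = 0.902) and 1 higher and 4 lower in HP against HR (adjusted p = 0.342). Genes of branched-chain amino acid catabolism were lower in HP than HR for 5 of 21 members, or 8 after rescaling (11 adjusted over the list alone), with Dbt at -1.07 and Ivd at -0.77 (adjusted p = 0.306 for the list with an estimated correlation). The clock genes Ciart and Bhlhe40 rose against ND in HP (1.63 and 1.32) and in HR (2.44 and 1.75). Of 18 genes in the clock list, 4 rose and 2 fell in HP against ND, at a median of -0.12. In HR against ND 3 rose and 0 fell, at a median of 0.36. Fabp4, Cidec and Pparg, genes of the adipocyte that fat-loaded liver also expresses, were higher in HP than HR by 1.51, 1.46 and 0.71. The hemoglobin genes Hba-a1 and Hba-a2, near-identical copies, rose in HP against ND by 1.45 and 1.84.

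The spermatid transcripts of eWAT ND 1 and HR 2 were weighed first. A diet group as the source was excluded, since the spermatid sum differed 724-fold within ND. Tissue of the testis mixed into the sample may account for them. The higher of the 2 adipocyte sums was 31.8% of the lowest among the other 7 libraries, as a mixture with any tissue needs. Insl3, a hormone gene of the testis looked at after the fact, had 1488 FPKM in ND 1 and 248.5 in HR 2. Among the other 7 libraries it was highest in ND 3, at 27.35 FPKM. Tissue of the epididymis was excluded for HR 2, where 7 epididymal genes summed to 0.28 FPKM, and stays open for ND 1, where they summed to 14631. A wrong label on the libraries stays open, because Adipoq was present at 202 FPKM or more in both and fat on another organ would give it too.

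Respiratory chain genes were higher in liver HP than HR by a median of 0.58. Transcript length and GC content, which correlated with the fold changes across genes at -0.233 and 0.212 (Spearman), were excluded as the whole cause, since 34 members stayed higher after their correction, against 35 before. Skeletal muscle in HP 2 and the scale of the values were excluded likewise as the whole cause. The median was 0.48 without HP 2, although 11 members were then called, and 30 members were higher after rescaling. HP 3, which also held muscle transcripts (19.9 FPKM), stayed in the fit without HP 2, so muscle in HP 3 was not tested. A change that goes with the prone group may remain as a hypothesis. Ribosomal protein genes and mRNAs coded in mitochondria (mt-Co1 left out), examined after the fact, were higher for 24 of 79 and 6 of 12, with medians of 0.48 and 0.8 (0.29 and 0.61 after rescaling).

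Macrophage genes were higher in eWAT HP than ND. Dilution of ND 1 and HR 2 by other RNA was excluded as the whole cause, since 17 members were higher without those libraries. A lower share of adipocytes would raise every other cell type alike. Macrophage genes rose more than endothelial genes by a median of 1.88 over the 7 libraries (two-sided permutation test over genes, which are not independent, p = 0.0088). That test does not measure the spread between libraries. Against this 1 comparator, fewer adipocytes did not account for the whole rise. Matrix and neutrophil and mast cell genes also rose, at medians of 1.15 and 1.32 against 1.8, so a part from fewer adipocytes stays open. More macrophages or more transcripts per macrophage may each remain as a hypothesis, and these data hold no cell counts.

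The 6 libraries of each comparison within a tissue make 10 splits, too few for a share under 0.05. In eWAT HP against ND the real split called 304 genes and the highest other 1, so that 1 split reached the real count. HR against ND called 0 (392 at an unadjusted p under 0.05, limma), a count that any split must reach, so the tally of splits decides nothing here. The highest other split called 2887, which points to a structure of the samples other than diet. HP against HR called 0 (679 at an unadjusted p under 0.05, limma), as did all 10 splits. In liver the real splits called 3372, 345 and 1185 genes and the highest others 1, 0 and 0, so that 1 split reached each real count.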
